A study of Drosophila melanogaster with 4 samples.

How the data were processed

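Su(Hw) ChIP-seq was carried out on formaldehyde-fixed embryos aged 16 to 24 h, with 2 ChIP and 2 input libraries per the labels. The labels do not say whether the libraries came from separate embryo collections. The deposited data used here are 1 peak list for the whole series, with the sequence, start and end of each interval and 1 score per interval. Per the file headers, positions refer to FlyBase release 5 and the intervals came from MACS. Per the submitters' processing notes, CASAVA 1.7.0.2 and 1.7.0.3, BWA, MACS2 and the build BDGP5 were used; their roles and settings are not given in the sources used here. Whether peaks were called on pooled libraries or per replicate, against which input, and at which threshold is likewise not given in the sources used here. These choices set how many weak peaks are listed and how one enriched region is divided into intervals.

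The score was deposited by the authors as the peak caller's own value, and no header says whether it is a transformed p, a q or another statistic. It was used only to describe, rank and filter peaks within this list. Because the first mitochondrial interval starts at position 0 and the narrowest intervals span 200 bp from start to end, starts may count from 0. Positions are printed as deposited, so starts may be 1 base lower than a genome browser shows, and width was taken as end minus start. No read counts were used, so the depth of each library is unknown. Intervals on shares cover counting error only.

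The reference at hand was a gene table of Release 6, another build than that of the peaks, so no coordinate of it was used and no peak was assigned to a gene. Of the analyses fixed before the data were examined, 6 needed a genome or annotation of release 5 and were not run: genomic features, the Su(Hw) motif, the motif by peak strength, leading short sequences, gene lists, and strength by genomic feature. The gene lists fixed for the last steps were therefore not tested, and no gene is named.

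Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9. Comparisons were restricted to the arms 2L, 2R, 3L, 3R, 4 and X. Arm lengths were the spans from the first to the last peak, since no assembly length of this build was used. Each arm's peak number was tested against its share of length by a two-sided exact binomial test with Benjamini-Hochberg adjustment at 0.05. Spacing was the share of peaks with another midpoint within 5 kb, compared with 1000 seeded uniform placements that kept the number of peaks per arm. A rule fixed in advance named the 15 strongest peaks, and the 5 densest 100 kb windows with ties. Other positions given in the text are outside that rule. Joined regions unite intervals whose edges are at most 1 kb apart and carry their highest score.

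The alternatives were the 2369 peaks with scores above the median of 33.7, joining within 500 bp, 1 kb or 10 kb, neighbour distances of 2 and 10 kb, placement within 1 Mb windows, and the major arms alone. Arm lengths counted from position 1, density after joining within 1 kb, permutation over 1 Mb windows, stretches of the length of chromosome 4 on the other arms and the tests on gaps between joined regions were added after the data had been seen. The statistics were tested on simulated data with the real spans and 4760 peaks, in 100 simulations per setting. The spacing test called 100% of simulated sets in which 10% of peaks had a partner within 4 kb and 8% of sets placed at random, and the test on gaps called 100% and 6%. The density test called chromosome 4 in 90% of sets with a true ratio of 0.5 and in 0 of those with equal density. These simulated peaks were independent, so that rate of false calls does not hold for peaks that cluster.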

Results

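Binding of Su(Hw), the Suppressor of Hairy-wing protein, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in Drosophila melanogaster embryos aged 16 to 24 h. Su(Hw) is a zinc-finger protein that binds the insulator of the gypsy retrotransposon and many other genomic sites. The embryos came from the y; cn bw sp strain, named for its marker mutations. The antibody was an affinity-purified rabbit polyclonal serum against Su(Hw). The labels list 2 ChIP libraries and 2 input libraries of the same stage. Their result is 1 list of 4993 peaks for the series. The list holds no value per library, so no replicate spread, depth or ChIP-to-input comparison could be computed from it, and the depth behind each peak is unknown. All tests below are across peaks in this list, which are not replicates of a condition. Peaks are named by position in FlyBase release 5 coordinates, because no gene annotation of that build was used here.

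Most of the listed peaks lay on the assembled chromosome arms, a share that was not set against the length of these arms in the assembly. The arms 2L, 2R, 3L, 3R, 4 and X carried 4760 peaks, or 95.3% of the list, at a mean of 40.4 peaks per Mb of the span they occupied. The Het sequences, which are assembled pieces of centric heterochromatin, carried 32 peaks. The unplaced scaffold collections U and Uextra carried 27 and 170 peaks, and the mitochondrial genome carried 4. The peaks on the major arms together covered 4.69% of the occupied span.

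Peaks ranged from short, weak intervals to broad, strong ones. On the major arms the median width was 681 bp, with an interquartile range of 354 to 1556 bp. The score the authors' peak caller gave each peak had a median of 33.7 on these arms and reached 1152.17. After intervals within 1 kb were joined, the medians were 1047 bp and 58.2. Scores of 100 or more were held by 1418 peaks, or 29.8% (exact Clopper-Pearson 95% interval 28.5 to 31.1%, counting error only). The 1190 weakest peaks had a median score of 10.4 and a median width of 272 bp. The 1190 strongest had a median score of 299 and a median width of 2438 bp. Across the 4760 peaks, width and score rose together, with Spearman's rho of 0.92 and Pearson's r of 0.92 on log10 values (two-sided permutation test, p = 0.0001, the smallest that 10000 permutations can give). Width and score come from the same peak calling, so they need not be independent and this p says nothing about binding itself. The file does not say which statistic the score is, so it was used only to describe, rank and filter peaks within the list.

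**Figure D1:**
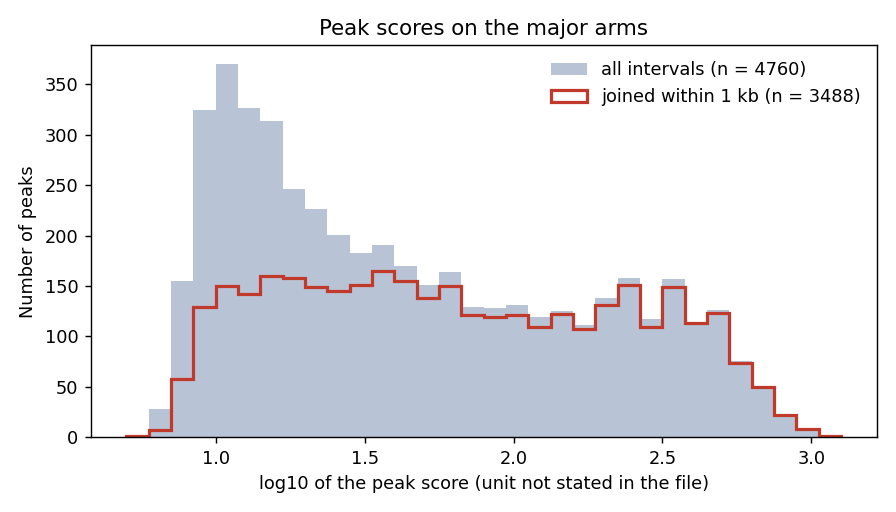
Number of peaks on the major arms (y axis) by the log10 of the authors' peak score (x axis), for all 4760 intervals (filled) and for the 3488 regions left after intervals within 1 kb were joined and given their highest score (red line). Scores between 10 and 17.8 held 1080 intervals but only 492 joined regions, while scores between 316 and 562 held 424 and 412.

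The 15 strongest peaks fell on 5 of the 6 arms. Chromosome arm 3L held 6 of them, 3R held 4, 2L and X held 2 each, chromosome 4 held 1, and 2R held none. The highest score, 1152.17, belonged to a peak on 2L from 2854213 to 2856910. It was followed by a peak on 3R from 27281489 to 27288220, with a score of 1039.64, and a peak on 3L from 22885292 to 22890908, with a score of 1029.31. The fourth lay on 3R from 3709154 to 3713603 (score 939.82), and the fifth on 3L from 22446495 to 22451659 (score 924.05). The sixth was the strongest peak of chromosome 4, from 431972 to 437426, with a score of 923.58. The other 9 had scores from 835.32 to 919.53. All 15 were broad, with widths from 2697 to 11808 bp. The widest of them, on 2L from 20282753 to 20294561, was also the widest interval in the list.

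The density of peaks was similar on the 4 large autosomal arms and lowest on chromosome 4, the small chromosome on which heterochromatin and genes are interspersed, although its value lay within the range of stretches of its length elsewhere. Chromosome 4 carried 25 peaks where its length predicted 46.7, a ratio of 0.54 (exact 95% interval 0.35 to 0.79), or 21.6 peaks per Mb. The X chromosome carried 840 peaks where 904 were predicted, a ratio of 0.93 (0.87 to 0.99), or 37.6 per Mb. The arms 2L, 2R, 3L and 3R had 40.6, 42.3, 40.3 and 42.0 peaks per Mb, with ratios from 0.998 on 3L to 1.047 on 2R.

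Each arm was compared with its share of the total length by a two-sided exact binomial test, with Benjamini-Hochberg adjustment over the 6 arms. Chromosome 4 passed the threshold of 0.05 (exact test, adjusted p = 0.0041). The X chromosome did not in the exact test (adjusted p = 0.054), nor did the 4 large autosomal arms (adjusted p from 0.216 to 0.971). The binomial test takes peaks as independent, which their close spacing contradicts, so peaks were also counted in stretches, a test added after the data had been seen. In full 1 Mb windows, X held 37.8 ± 11.8 peaks (SD, 21 windows) and the autosomal arms had means from 40.8 to 42.2 with SDs from 7.60 to 13.02 (two-sided permutation test of X against the other windows, p = 0.159, adjusted p = 0.795). Among 100 stretches of the length of chromosome 4 on the other arms, with 47.0 ± 12.0 peaks (SD), 5 held 25 peaks or fewer, so the call on chromosome 4 was lost (two-sided exact rank p = 0.119). Where those 5 lay is not given here. The full 1 Mb windows with fewest peaks were those nearest the centromere on 3L (2 peaks), 2R (15), 2L (19) and X (19). The call was also lost when peaks within 10 kb were joined, with a ratio of 0.61 and an exact-test adjusted p of 0.353. The median gap was 9.78 kb over all arms and 28.5 kb on chromosome 4. Joining over 10 kb thus unites more peaks where they are dense, which can by itself move the ratio toward 1. Lengths were taken from the first to the last peak of each arm, which leaves out arm ends without peaks.

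**Figure D2:**
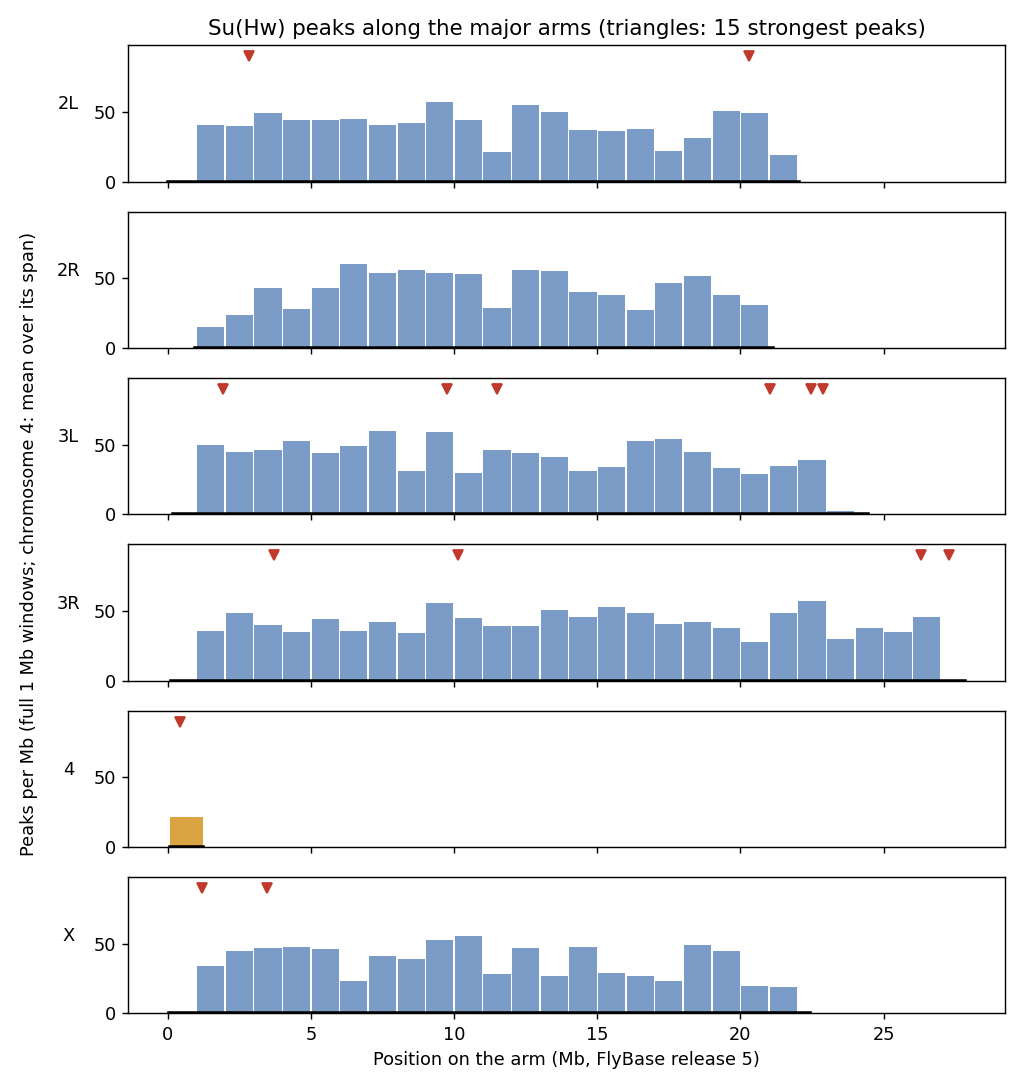
Peaks per Mb (y axis) along each arm (x axis, position in Mb, FlyBase release 5). Blue bars are full 1 Mb windows, the orange bar is the mean of chromosome 4 over its span, black lines are the span from the first to the last peak, and red triangles mark the 15 strongest peaks (no error bars, 1 peak list). Chromosome 4 stands at 21.6 peaks per Mb, and the windows with most peaks, on 2R from 6 Mb and on 3L from 7 Mb, hold 60 each.

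Peaks lay closer together than random placement gives. On the major arms, 57.5% of peaks had another peak midpoint within 5 kb. In 1000 random placements of the same number of peaks per arm this share was 33.3% on average, and 35.7% at most (two-sided permutation p = 0.002, the smallest that 1000 placements can give). Neighbouring intervals were separated by a median of 9.78 kb, and 1272 of 4754 gaps, or 26.8%, were at most 1 kb. Joining intervals across such gaps gave 3488 regions, of which 2620 held a single interval and 868 held 2140 intervals between them. The regions with most intervals, 7 each, lay on 2R from 9419064 to 9429833 and on X from 19049877 to 19058654.

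The comparison of midpoints changed with the set of peaks. Among the 2369 peaks scoring above the median, 19.5% had a neighbour within 5 kb against 18.3% at random (permutation p = 0.238), and among the joined regions 20.0% did, against 25.7% at random (permutation p = 0.002), which is the opposite direction. Midpoints of broad or joined regions cannot lie as close as random points, so gaps between the edges of joined regions were also compared, a test chosen after the data had been seen. Of 3482 such gaps, 17.3% were between 1 and 5 kb long, against 12.1% in placements that kept every gap above 1 kb (permutation p = 0.002), and for the peaks scoring above the median the shares were 12.2% and 7.91% (permutation p = 0.002).

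**Figure D3:**
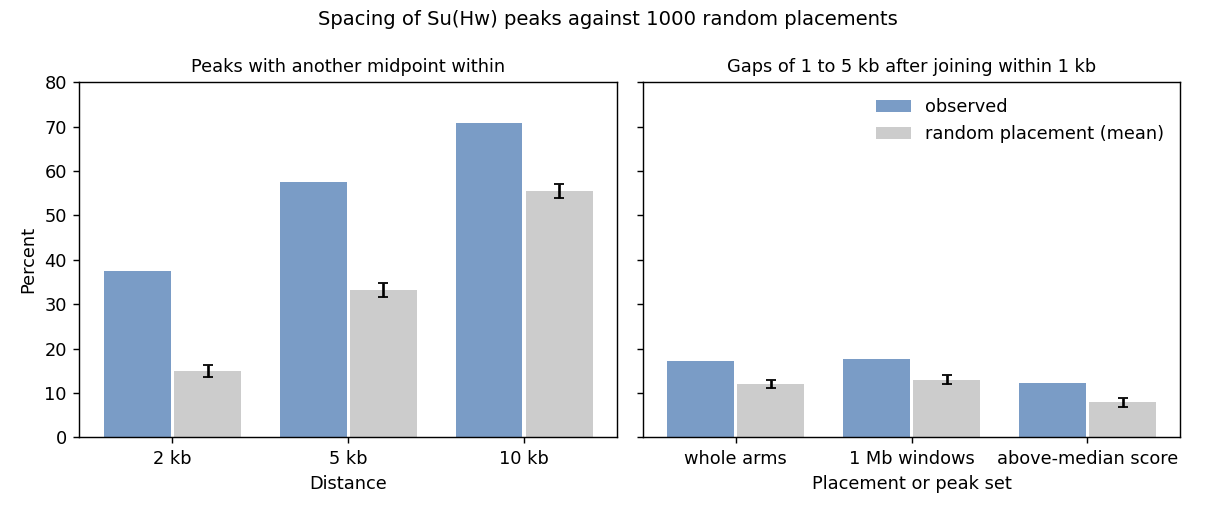
Left, percent of peaks (y axis) with another peak midpoint within 2, 5 or 10 kb; right, percent of gaps between joined regions that were 1 to 5 kb long, over whole arms, within 1 Mb windows and for peaks scoring above the median. Blue bars are observed, grey bars the mean of 1000 random placements with its central 95% range; every blue bar lies above that range (57.5% against 33.3% at 5 kb).

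The densest stretches of 100 kb were found on 2L, 2R, 3L, 3R and X. The windows with most peaks, 17 each, were 8700001 to 8800000 on 2R and 15300001 to 15400000 on 3R. They held 8 and 11 joined regions, with highest scores of 273 and 275. The windows 20200001 to 20300000 on 2L and 19000001 to 19100000 on X held 16 peaks each. The 2L window contained the widest peak, and intervals covered 31.2% of it. A further 3 windows tied at 15 peaks, on 2R from 9400001 to 9500000 and on 3L from 4400001 to 4500000 and from 22300001 to 22400000. Of 1184 windows, 111 held no peak, against 24.0 on average and 39 at most in random placements. The highest count of 17 lay above the median of the highest counts in random placements (12) and below their largest (19). How often random placements reached 17 is not given here.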

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

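The 4 groups of sequences below carry peaks, more than 3 each, but entered none of the tests above, which is why they are listed here. No control level was at hand to set them against, and values of the major arms are only given beside some of them. The tests of neighbour scores, of gaps between joined regions, of chromosome 4 after joining within 1 kb or against stretches of its length, and of mitochondrial coverage were chosen after the results were seen.

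The mitochondrial genome carried 4 peaks, with scores of 257.95, 104, 244.84 and 80.4 in order of position. They covered 97.5% of the span from position 0 to 14791, which the peaks themselves set, whereas peaks covered between 2.50% of the span on chromosome 4 and 5.21% on 2R. The longest ran from 0 to 9006. More mitochondrial DNA in ChIP than in input libraries could give such long intervals. No peak lies beyond 14791, but no read counts were used, so that absence does not speak for or against this explanation. The spans of the other sequences are also set by their peaks. Intervals covered 0.33% of the span on 2RHet, with 7 peaks, and 100% by construction on 2LHet, with 1. The mitochondrial share therefore describes nearly continuous intervals up to 14791. The length of the whole sequence was not used here, so the share of it that they cover is unknown and the test decides nothing. An excess of mitochondrial DNA and binding along the molecule cannot be told apart.

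The Het sequences carried 32 peaks with a median score of 18.4. Their 3 strongest lay on 2RHet from 369005 to 372989 (score 608), on 3LHet from 1282877 to 1287044 (score 443) and on 3RHet from 1521316 to 1527147 (score 411). The scaffold collection U carried 27 peaks, of which the strongest, from 6832539 to 6834296, scored 565. Uextra carried 170 peaks, narrower than those of the major arms (median width 364.5 against 681 bp), with a similar median score (30.5 against 33.7). Scores of 100 or more were held by 8.24% of them (exact 95% interval 4.58 to 13.4%) against 29.8% on the major arms.

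Many weak peaks lay within 1 kb of stronger ones. Of the 1195 peaks on the major arms scoring at most 14.01, 61.3% had another interval within 1 kb, against 45.1% when scores were permuted among the peaks of each arm. Among the weak peaks with such a neighbour, the nearest one had a median score of 106, above the highest of 1000 permutations (48.9). A candidate explanation is that edges of strong regions were listed as separate weak intervals. Secondary binding near strong sites would place weak peaks in the same way, and the list alone does not separate them. Division across gaps of at most 1 kb does not account for all close spacing. Of gaps between joined regions, 17.3% were 1 to 5 kb long against 13.6% in the highest random placement. Density over 1 Mb windows does not either, since within such windows that share was 17.7% against at most 14.5%. Unjoined intervals placed within 1 Mb windows gave at most 37.2% of peaks with a neighbour within 5 kb against 57.5% observed, which divided intervals also raise. Division across wider gaps and density differences at a finer scale were not tested as causes of the close spacing. More 100 kb windows were empty (111) than in any random placement (at most 39), which divided intervals can also raise.

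Chromosome 4 had 25 peaks where 46.7 were predicted, but 5 of 100 stretches of its length on the other arms had as few (exact rank p = 0.119). Uneven spacing of peaks along the genome therefore stays open. Joining within 10 kb gave a ratio of 0.61 and ended the call, but such joining can by itself move the ratio toward 1. After joining within 1 kb the ratio was 0.47, and chromosome 4 had 1.56 intervals per region against 1.36 elsewhere, which argues against fewer intervals per region as the cause. The mean score percentile was 46.8 on chromosome 4 and 50.0 on the other arms (difference -3.27, 95% bootstrap interval -15.1 to 8.91, permutation p = 0.575). Its median score was 18 (95% interval 15.6 to 117.9) against 30.1 to 36.4 on the other arms, while 32% of its 25 peaks scored 100 or more. Weaker read coverage could lower scores but also hide weak sites, which raises the mean rank of those left. The score ranks therefore cannot decide on it. A true lower number of Su(Hw) sites on this chromosome, and repeats in which reads cannot be placed, stay open and were not tested.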

How the results depend on the processing

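Joining intervals within 500 bp moved the median width from 653 to 904 bp and the median score from 33.2 to 50.1, and keeping only the major arms moved the median width to 681 bp. The number of peaks moved by less than 1.5 times under either (3918 and 4760, from 4993). The share of peaks with a neighbour within 5 kb was 57.5%; it was 19.5% for peaks scoring above the median, no longer above random placement (permutation p = 0.238), and 20.0% after joining within 1 kb, reversed to below the random 25.7%. The tests on gaps between joined regions, added after the data had been seen, kept the direction over whole arms, within 1 Mb windows (17.7% against 13.04%) and for peaks scoring above the median. So did distances of 2 and 10 kb and placement within 1 Mb windows. Chromosome 4 kept its call in the exact test for peaks scoring above the median (ratio 0.39), with lengths from position 1 (0.51) and after joining within 1 kb (0.47); joining within 10 kb left 14 peaks and ended it (0.61, adjusted p = 0.353), as did its rank among stretches of its length on the other arms (0.53, exact p = 0.119). No other arm passed the threshold under any alternative run, and chromosome 4 was not tested by 1 Mb windows, having no full one. No paired analysis was possible because the peak list holds no values per library, and no replicate could be left out for the same reason. The other settings of the 6 analyses that need a release 5 genome were not run. Assembly lengths of the arms were not used, so the span could not be set against them.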

Other observations

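All tests in this part were chosen after the results were seen. Listed peaks were sparse next to the centromere. Whether reads can be placed there was not tested, so this need not mean fewer Su(Hw) sites. In the 10% of the occupied span nearest the centromere, 2R held 39 peaks against 71 to 111 in the other equal parts of the arm, 3L held 46 against 73 to 126, and X held 44 against 58 to 116. On 3R it held 99 against 102 to 141, and on 2L it held 77, level with the lowest of the others (77 to 106). Relative to the mean part of each arm, the ratio averaged over the 5 arms was 0.63 (two-sided exact test over all choices of 1 part per arm, p = 4e-05). Neighbouring parts are not independent and this region was picked after its counts were seen, so the p overstates the evidence. The 5% nearest the centromere held 22 peaks on 2L, 15 on 2R, 6 on 3L, 25 on 3R and 17 on X, where even shares would be 44.8, 42.8, 49, 58.3 and 42. The adjoining 5% held 55, 24, 40, 74 and 27, and the arms went both ways: without the innermost 5%, the ratio was 0.54 on 2R, 0.62 on X, 0.78 on 3L, 1.20 on 2L and 1.23 on 3R. Their average of 0.88 did not pass the exact test (p = 0.27). Exact binomial tests, which take peaks as independent, passed on 2R (adjusted p = 0.0055) and X (adjusted p = 0.024) and not on 3L, 2L and 3R (adjusted p from 0.121 to 0.172). The 10% of 3L, from 22035253 to 24464184, held the peaks with scores of 1029.31 and 924.05, which are among the 15 strongest.

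Between the first and last peak of each arm, the longest gaps on 2L, 2R, 3L and X were near the centromere. This was noted after the values were seen. These gaps measured 361 kb on 2L (21684005 to 22044626), 568 kb on 2R (1011102 to 1579430), 655 kb on 3L (23800800 to 24455315) and 336 kb on X (21508129 to 21843870). Whether reads can be placed within these gaps was not tested. Arm ends beyond the outermost peaks were left out. On 2R the first peak starts at 936731, so the stretch from position 1 to it is longer than any gap listed here. On 3R the longest, 270.0 kb, lay in the middle of the arm (15467379 to 15737375). On chromosome 4 a stretch of 273 kb (685893 to 959059) held none.

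The share of peaks with another interval within 1 kb did not follow strength in a single direction. It was 61.3% in the 1190 weakest peaks, 40.3% and 28.2% in the 2 groups of 1190 ranked above them, and 50.0% in the 1190 strongest.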
